A study of Mus musculus with 31 samples.

How the data were processed

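RNA levels in mouse ES cells with and without Srap1, and control IgG libraries, were taken from the authors' deposited files. Per the labels, the ES cells were of mixed 129 and C57BL/6 background, the RNA was depleted of ribosomal RNA, and libraries were amplified for 12 cycles of PCR. Cells for DIP and ChIP were at passages 3 to 5. The submitters' processing notes name Trim Galore 0.3.5, Bowtie 0.12.8, MACS2 2.1.1, Cufflinks 2.2.1.0 for RNA and Bismark 0.14.5 for the DNA libraries, with build mm9 for RNA and both mm9 and mm10 for DNA. They give no order or settings.

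The RNA values are FPKM with lower and upper bounds, per the file headers, which are those of a Cufflinks table of loci. Every locus carries a number given by the program, so loci were assembled separately in each library, and their ends differ between tables. FPKM is scaled within a library, and the authors' values carry no scaling between libraries. The IgG DIP file has 1 row per aligned read with a score for mapping quality from the authors' alignment, and positions that run to the ends of mm9 chromosomes. The IgG ChIP file gives the authors' windows as chromosome, start and end, per the file headers, with no score, and how they were selected is not given in the sources used here. Positions of RNA loci and windows are printed as the files give them, and those of read blocks are counted from 1.

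Samples were grouped by title, with replicate numbers as the labels give them or in order of listing. The labels name no separate cultures. Depth was read from the bounds of FPKM, taking the distance from the value to the upper bound as 2 standard deviations of a Poisson count. The implied fragment number was whole within 0.02 for 26.3% to 27.3% of loci in the wild-type tables and 33.4% in the knockout table. It is therefore an approximation, and at some loci it fails. In the knockout it was 7.1e-08 at a locus with 2.28 FPKM (chromosome 8, 87541679 to 87549142). It was 3.02 at a locus with 76.0 FPKM (chromosome 14, 21522298 to 21523639). Wild-type tables were compared by implied fragment numbers at loci of at least 300 bases, with 200 simulations per pair. Variation of 10% between samples would have given a scaled median difference of 1.42 to 1.51 standard errors, with a lower limit of 1.05 to 1.15, so variation of that size is not excluded for every pair.

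Loci of the first wild-type table were paired with those of each other table by the best mutual overlap of at least 80% of both (bedtools 2.31.1). Loci with at least 1 FPKM in 2 tables were kept and compared as log2(FPKM + 1), which understates the change of low loci. The rule for calls, fixed before the data were examined for the case of a knockout with 1 library, asks for a knockout value outside the range of the 4 wild-type values and a ratio of at least 2. The linear model planned for replicated groups was fitted with limma 3.58.1 in R 4.3.3 as an alternative. It treats the 4 wild-type tables as replicates, which leaves 3 residual degrees of freedom, and assumes that the lone knockout sample varies like them. Loci counted at a Benjamini-Hochberg adjusted p under 0.05. Gene lists, the level of Srap1 and other named genes had been planned and were not analysed, because the files pair no locus with a gene; the gene table at hand is of GRCm38.p6 and was used to look for names only. The rule for named items was the highest and lowest log2 ratios past the threshold with a mean of at least 5 FPKM. Its exclusion of small RNAs by name was replaced by a minimum width of 300 bases after the values were seen, 2 loci that rose and 1 that fell were taken from it, and the chromosome 17 locus was added for its share of the fragments.

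The pairing and calling were tested on simulated data made from 7660 loci of the first wild-type table, with 4 control tables and a test table of 10 times the depth. Pairing was correct for 99.9% of 7572 paired loci. Loci raised 2-fold were called in 46% of 50 cases and those raised 4-fold in 100%. Loci lowered to 0.5 were called in 38% and those lowered to 0.25 in 98%. Of 7372 unchanged loci 1 was called. The limma fit called 2% of loci raised 2-fold, 54% of those raised 4-fold, 4% of those lowered to 0.5, 36% of those lowered to 0.25, and 0 of the unchanged loci. The simulated loci kept their ends to within a few percent, which the real tables do not. They also varied by counting noise alone. The rates therefore describe loci that pair and differ by counting noise only. Among the 224 real paired loci, 2 to 10 were called when each wild-type table was set against the other 3.

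IgG DIP reads were counted in 10 kb bins that hold at least 1 read with a mapping quality of at least 30. Blocks were stretches with coverage of at least 15 such reads. Windows of the IgG ChIP and wild-type RNA regions were placed 1000 times at random on the same chromosomes with a fixed seed, from 3 Mb onwards on all chromosomes but Y, and a read counted with 1 base inside. Tests used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9. The alternatives tried were other scalings, pseudocounts, filters and overlaps, each library left out, distinct reads, other bins and other placements.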

Results

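The study set Srap1 knockout mouse embryonic stem (ES) cells beside wild-type ES cells derived together with them. Srap1 is a protein with a SRAP domain, a fold that acts on DNA, and the title of the series places it in the removal of 5-methylcytosine that Tet enzymes have oxidized. The labels describe 31 samples in 18 groups, covering immunoprecipitation of DNA with antibodies to modified cytosines (DIP), chromatin immunoprecipitation (ChIP) of tagged Srap1, RNA sequencing, and bisulfite sequencing of embryos. The measurements described here come from 8 of these samples. They are 4 wild-type RNA libraries, 2 Srap1 KO RNA libraries, 1 control immunoprecipitation of Srap1 KO DNA with IgG (IgG DIP), and 1 control ChIP with IgG. The other 23 samples were not analysed here, so no modified cytosine was compared between the genotypes.

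The RNA tables list loci assembled from the reads of each library, with positions on mouse build mm9 and a level in FPKM. FPKM counts fragments per kilobase of transcript, scaled to the total of the library. The transcript length it uses is not the width of the locus. The RNA tables pair no locus with a gene name, and of 143213 distinct locus IDs 0 matched a gene. Srap1 itself was therefore not examined in these tables, and the genotype of the libraries rests on the labels. Loci are given by position, with no gene, exon or intron assigned. The 2 tables labelled Srap1 KO were identical in every value and were counted as 1 sample. The 4 wild-type tables differed, at the median locus, by less than the sampling noise of their fragments allows. Over the 6 pairs of wild-type tables, 77 to 94 loci had the same ends within 5 bases and at least 10 implied fragments in each table. The scaled median size of the difference was 0.884 to 1.27 standard errors, against an upper limit of 1.20 to 1.32 in simulations with counting noise alone. Between 1 and 6 of these loci per pair differed by more than 4 standard errors, which counting noise alone would seldom give. At those loci the tables varied by more than counting noise, or the implied fragments were wrong. The compared loci were picked for their matching ends, so the test cannot show that the tables come from 1 sample. As a cautious choice, the wild-type tables were also counted as 1 sample. The test does not exclude variation of 10% between samples for every pair, so their range is given beside the mean level of each named locus. With n = 1 for the knockout no difference has a replicate check, and no p-value of a locus is given.

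The wild-type and knockout RNA tables differed in depth and in makeup. The knockout table held 143073 loci, and each wild-type table held 8882 to 9295. The median locus width was 486 bases in the knockout and 1978 to 2040 bases in the wild type. The intervals around the FPKM values imply 895779 to 926460 fragments in each wild-type table and 10804715 in the knockout table. A locus at chromosome 17, 39979940 to 39985777, held 61.4% to 62.2% of the implied fragments in the wild-type tables and 3.51% in the knockout table. Outside this locus the wild-type tables held 338453 to 355077 implied fragments. All RNA was depleted of ribosomal RNA, per the labels. Whether the chromosome 17 locus is ribosomal was not examined, since no gene was assigned to any locus. The mitochondrial chromosome had 1 to 2 loci in each wild-type table, with a summed level of 6569 to 29149 FPKM, and no locus in the knockout table. The Y chromosome had 2 to 4 loci in the wild-type tables and 86 in the knockout table.

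The comparison of the genotypes asks which transcribed loci differ without Srap1. At 224 loci that could be paired across all tables by at least 80% reciprocal overlap, 79 were higher and 36 lower in the Srap1 KO. A locus counted when the knockout value lay outside the range of the 4 wild-type tables and the log2 ratio of FPKM + 1 was at least 1 in size. By the same rule, 2 to 10 of these loci were called when each wild-type table was set against the other 3. The knockout value lay outside the wild-type range at 82.1% of the loci, against 40% if all 5 tables were exchangeable. The 4 tables were counted as 1 sample, so this range and the 2 to 10 calls may reflect technical noise alone. They may understate the variation between samples, and any other sample may lie outside the range. The whole set of ratios was shifted upwards, with a median log2 ratio of 0.52 and quartiles of -0.21 and 1.23. When this shift was removed by median scaling, 34 loci were higher and 51 lower, so the direction in which most calls went reversed. Quantile normalization gave 30 higher and 30 lower. Genotype, depth and the makeup of the tables change together here. Read length or processing may change with them, since the shortest locus was 21 to 22 bases in the wild-type tables and 50 bases in the knockout. The difference cannot be assigned to the genotype.

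Among loci of at least 300 bases, the highest ratio was at chromosome 14, 51427119 to 51427443. Its level was 46278 FPKM in the knockout against a wild-type mean of 2215 FPKM, with a range of 2120 to 2324 FPKM, a log2 difference of 4.39. After median scaling the difference was 3.88. The next was chromosome 8, 53281175 to 53282437, at 232 FPKM in the knockout against 22.2 FPKM in the wild type, with a range of 21.4 to 23.8 FPKM. This log2 difference was 3.33, and 2.83 after median scaling. The lowest ratio was at chromosome 11, 108872957 to 108873428, where the knockout had 89.5 FPKM and the wild type 11510 FPKM, with a range of 11221 to 11787 FPKM. The log2 difference was -6.99, or -7.50 after median scaling. The locus on chromosome 17 that held most wild-type fragments had 3046 FPKM in the knockout and 49281 FPKM in the wild type, with a range of 47660 to 50078 FPKM, a log2 difference of -4.02. After median scaling it was -4.52. These 4 loci kept their direction under every scaling that was run, although quantile normalization left the chromosome 17 difference at -0.52, under the threshold, and put the chromosome 14 difference at 7.96.

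**Figure D1:**
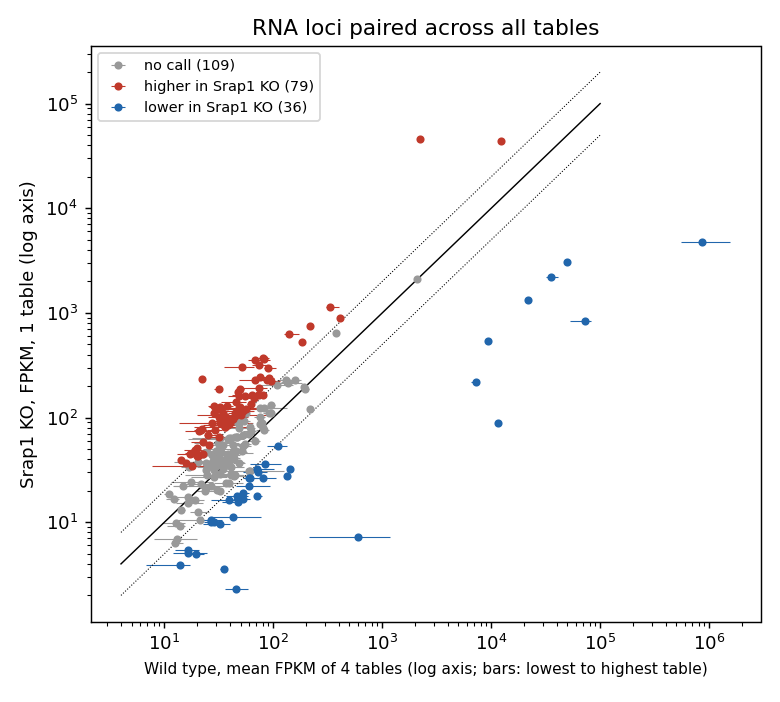
FPKM of 224 paired RNA loci in the Srap1 KO table (vertical, log axis) against the mean of the 4 wild-type tables (horizontal, log axis). Bars run from the lowest to the highest wild-type table, the solid line marks equal levels and the dotted lines a ratio of 2 either way; 79 loci were called higher and 36 lower.

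The ratios depended on the width of the locus. At 10 loci under 300 bases the median log2 ratio was -2.49, and 6 were called lower and 3 higher. At 29 loci of 300 to 1000 bases it was 1.36, with 18 higher and 2 lower. At 81 loci over 10000 bases it was 0.31, with 17 higher and 12 lower. Across the paired loci, Pearson's correlation of log2(FPKM + 1) was 0.974 to 0.984 between wild-type tables and 0.675 to 0.696 between a wild-type table and the knockout. Spearman's correlation was 0.852 to 0.911 and 0.588 to 0.610. These correlations run across loci, which are not independent replicates.

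Of 3715 merged regions present in all 4 wild-type tables, 254 (6.84%) had no overlapping knockout locus. Of the 3712 on numbered and sex chromosomes, 93.2% had one, against a median of 21.1% over 1000 random placements of the same widths (95% of placements 19.8% to 22.4%), a test added after the counts were seen. For regions under 3000 bases it was 77.9% against 13.6%, and for the wider ones 99.1% against 24.0%. In the other direction, 96427 of the 143073 knockout loci (67.4%) overlapped no wild-type region. The median level of these was 3.79 FPKM, against 7.27 FPKM for the other knockout loci, and 71.3% of them were below the 5th percentile of wild-type levels, 6.98 FPKM. The lowest listed level was 1.55 to 2.11 FPKM in the wild-type tables, so such levels could be listed there, but seldom were at this depth. Absence of these loci from the wild type cannot be inferred. Of the knockout loci outside wild-type regions, 2220 had at least 20 FPKM and at least 300 bases.

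The IgG DIP library of Srap1 KO DNA held 9127504 aligned reads, 93.8% of them 50 bases long, with 4565208 on the forward strand. A start and strand already seen in another read made up 4.24% of reads (95% exact binomial interval 4.23% to 4.25%). Intervals given for reads and windows cover counting error only. Mapping quality was under 30 in 20.7% of reads (20.7% to 20.7%). Among reads with a quality of at least 30, the median per 10 kb bin was 30 on the autosomes together, and ranged from 25 on chromosome 3 to 37 on chromosome 11. It was 9 on X and 6 on Y, or 0.30 and 0.20 of the autosomal value. With all mapping qualities the X value was 0.43 of the autosomal one. The wild-type IgG DIP library was not analysed here, so the densities describe this library alone.

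Reads of the IgG DIP library were stacked in 6 short blocks on chromosome 6 between 87864507 and 87886317 (mm9). The blocks lay at 87864507 to 87864690, 87867831 to 87867978, 87871518 to 87871645, 87875624 to 87875805, 87883233 to 87883429, and 87886082 to 87886317. They were 128 to 236 bases wide and 1075 bases together. Their mean coverage was 95.3 to 145 reads per base, while the mean over the genome was 0.136. The blocks held 2741 reads of quality of at least 30, or 2550 per kb. The sequence between them had 3.95 reads per kb and the 100 kb on either side 4.53 reads per kb. A search of the assembled chromosomes for groups of at least 4 blocks of 80 to 400 bases within 30 kb found 4 groups. This was the only group of the 4 with gaps below 2 times the density of the flanks. In the RNA tables the same interval was transcribed in both genotypes. The knockout locus ran from 87864013 to 87886638 at 35.3 FPKM (32.8 to 37.8 FPKM in the deposited interval). In wild-type replicate 4 a locus from 87863941 to 87886614 had 28.4 FPKM (21.6 to 35.1 FPKM). In the other wild-type replicates the transcribed loci covered parts of the interval, at 26.0 to 76.5 FPKM.

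**Figure D2:**
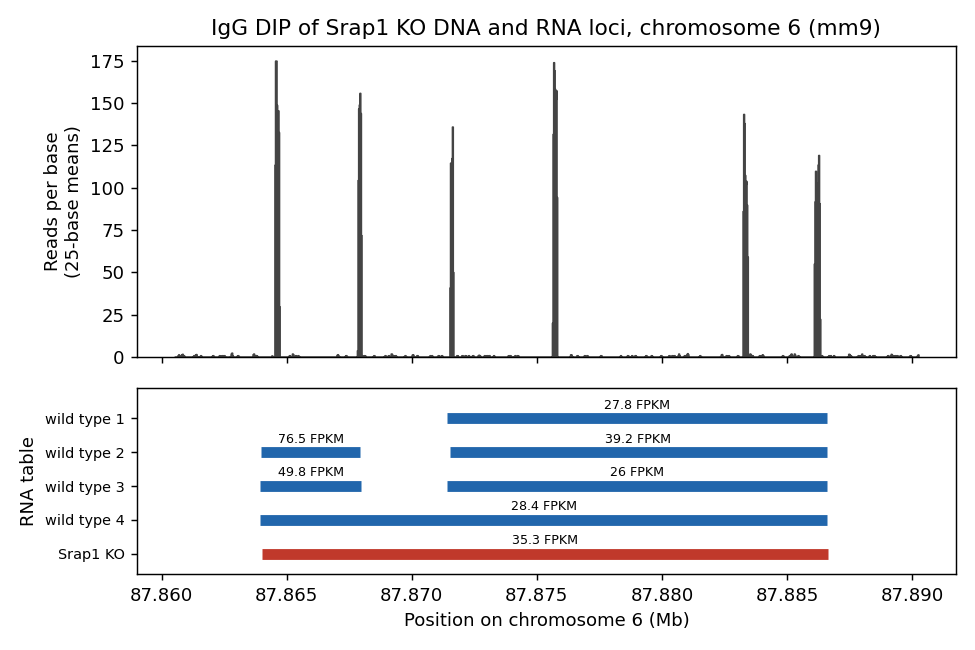
Coverage of the IgG DIP reads of Srap1 KO DNA with mapping quality of at least 30 (top, reads per base) and assembled RNA loci with their FPKM (bottom, a bar per locus, wild type in blue and Srap1 KO in red) along chromosome 6 of mm9, in Mb. The 6 blocks reach a mean of 95.3 to 145 reads per base and the sequence between them stays near 0, while RNA loci span the whole interval in wild-type replicate 4 and the Srap1 KO and parts of it in the other replicates.

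The IgG ChIP list held 1730 windows with no score. Of these, 1729 were 2000 bases wide, all began on a 2 kb grid, and 6 pairs were adjacent. Chromosome X carried 289 windows, or 16.7% (exact binomial interval 15.0% to 18.5%), and made up 6.34% of the sequence considered. The ratio of these shares was 2.64 for X and 0.562 to 1.13 for the autosomes. No window overlapped the interval of the read blocks on chromosome 6.

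**Figure D3:**
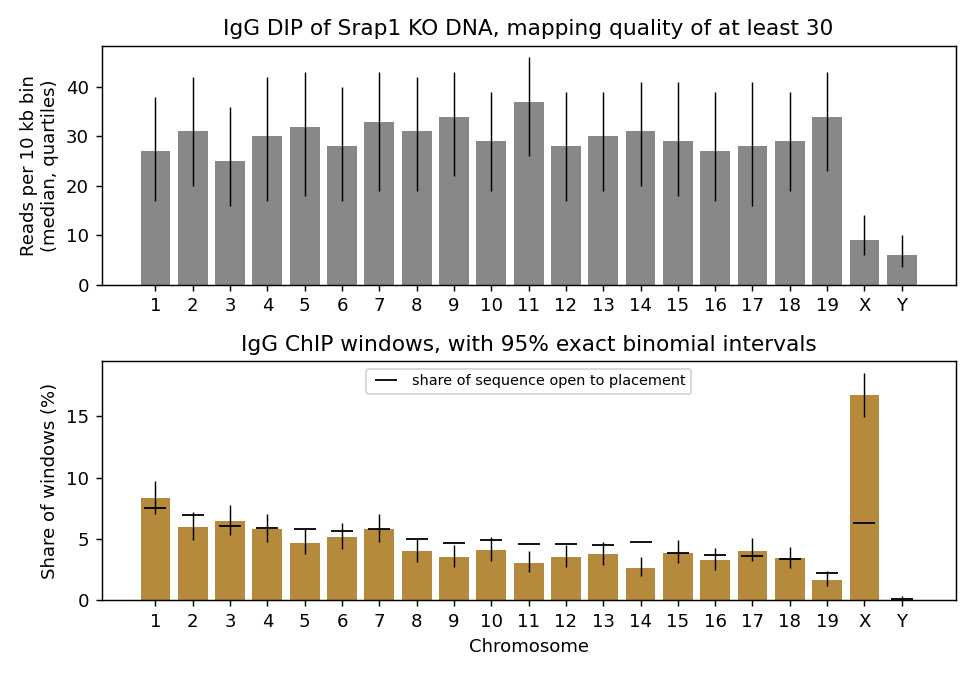
Median reads per 10 kb bin of the IgG DIP library of Srap1 KO DNA by chromosome, with quartiles as bars (top), and the share of the 1730 IgG ChIP windows on each chromosome in percent, with 95% exact binomial intervals and the share of sequence as a dash (bottom). X has the fewest DIP reads per bin after Y, 9 against 25 to 37 on the autosomes, and the largest share of windows, 16.7%.

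The control libraries were then compared with each other, to ask whether windows of the IgG ChIP also collect reads in the IgG DIP. They did not. The windows held 9677 IgG DIP reads, against a median of 11294 over 1000 random placements on the same chromosomes. The ratio was 0.857, outside the 0.969 to 1.07 that holds 95% of placements. The one-sided permutation p for more reads than chance was 1, and that for fewer reads, a direction chosen after the value was seen, was 0.001, the smallest these placements can give. The counts took in DIP reads of every mapping quality, and no alternative kept only those of at least 30. The X windows held a smaller share of reads under 30 than random placements on X, 32.5% against a median of 46.1%. Whether the lower count holds for reads of at least 30 was not tested. The libraries came from different input material, crosslinked chromatin and purified DNA.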

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

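The tests in this part were chosen after the read blocks were seen; only that on short alignments was set before its result was known. Of 11 quantities examined over the 4 wild-type RNA tables, 3 had a table far from the others, where chance gives about 1 in 20. The summed level of mitochondrial loci was 29149 FPKM in wild-type replicate 4 and 6569 to 6788 FPKM in the other 3. The implied mitochondrial fragments did not show this rise, with 4840 in replicate 4 and 4551 and 4563 in replicates 1 and 3. Replicate 2 had 2327 and lay far below the others. It listed 1 mitochondrial locus where the other wild-type replicates listed 2 each, so its lower sum need not be a lower RNA level. The locus on chromosome 8 from 53281175 to 53282437 had 23.8 FPKM in wild-type replicate 4 and 21.4 to 21.7 FPKM in the others.

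The last item is a signal in a control library that entered no comparison of the genotypes. The 6 read blocks on chromosome 6 held 563 times the read density of the 100 kb on either side. A continuous extra copy of the region is argued against by the sequence between the blocks, at 0.874 of the flanks. Reads shared with other copies are argued against by mapping quality, since 0% of the block reads had a quality under 30 (a count of 0 in 2741 reads allows up to 0.109%). The search did not rule out such reads, since in 10 of the other 43 blocks it found they made up more than 50%. Repeated amplification alone is argued against by the 237-fold density that remained with 1 read per start and strand, although 58.2% of block reads repeated a start. A single spliced copy inserted in the genome of the strain would give a density close to that of the flanks, not 563 times it.

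A candidate explanation is DNA of a spliced copy in the library, such as a cloned or amplified coding sequence. Reads across a junction would then align only in part, if the authors' alignment allowed that. Its settings are not given. In the blocks, 24.8% of reads (95% exact binomial interval 23.2% to 26.4%) were aligned over fewer than 49 bases, against 2.78% of all reads of the same quality. Of these short alignments 87.8% ended within 5 bases of a block edge, against 11.5% of the longer ones. The edges were drawn from the coverage of these same reads, so the 87.8% is not independent support for a spliced copy. The knockout RNA locus over the same interval began 494 bases before the first block and ended 321 bases after the last, so the ends of the transcribed locus are not among the blocks. The labels record cells in this series that stably express tagged Srap1, but whether the interval holds Srap1 was not examined, because no mm9 annotation was used here. If it did, the knockout RNA locus at 35.3 FPKM would bear on the genotype label behind the whole RNA comparison. The source of the DNA stays open, as does a difference in genotype, since the wild-type IgG library was not analysed here.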

How the results depend on the processing

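Overlap settings, width and level limits, fixed regions, all mapping qualities, merged windows and placements in bins with reads were chosen after seeing the data. The count of 115 changed loci stayed within 1.5 times its value in 11 of 16 alternatives; another 4, namely both filters and either identical knockout table left out, moved no locus and test nothing. Without each wild-type library it was 132 to 145, of 277 to 297 loci paired. The limma fits are among the 11. They treated the wild-type tables, counted here as 1 sample, as replicates and took the lone knockout to vary like them. Their counts are therefore not used as support. The count of changed loci was 60 with quantile normalization and 334 of 833 loci at an overlap of 0.5. It was 66 of 124 at 0.9, and 51 of 83 with a wild-type mean of at least 50 FPKM. The overlap and level settings change how many loci are compared. Implied fragments in fixed wild-type regions gave 1288 of 3059, a count that rests on numbers that fail at some knockout loci. The split into higher and lower loci was 79 to 36, 34 to 51 with median scaling and 30 to 30 with quantile normalization. The median correlation of wild-type tables with the knockout was 0.691, 0.721 at an overlap of 0.5 and 0.664 for loci of at least 300 bases. The X to autosome ratio of DIP reads, 0.30, was 0.282 in 100 kb bins and 0.429 with all mapping qualities; the cause was not tested. The blocks on chromosome 6 were 237 times the flanks with distinct reads and 499 times with all qualities. Of 50 alternatives for the named loci, 22 only select loci, repeat the value and test nothing; in the other 28, 8 moved beyond the wild-type spread and 0 reversed. The chromosome 11 locus is not paired at an overlap of 0.9, and that on chromosome 8 is under 50 FPKM in the wild type. The DIP density in ChIP windows was 0.849 to 0.859 in its 3 alternatives and the X share of windows 16.6% after merging. No paired analysis was possible because the labels of the RNA groups share fewer than 2 numbers and the knockout tables are identical. Not run were exclusion of genes by name, gene lists, the Srap1 level and limits on a window score, which the files do not give. Loci of low level are listed seldom at the wild-type depth.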

Other observations

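The tests of repeated sequence and of transcription in this part were set before their results were known, and those of depth and of matched width after. Of the wild-type regions that lack a knockout locus, 215 of at least 300 bases had genomic reads in the IgG DIP library. At 70.2% of them (95% exact binomial interval 63.6% to 76.3%) more than 50% of those reads had a mapping quality under 30, against 4.94% (4.24% to 5.73%) of 3418 regions with a knockout locus. The ratio of these shares was 14.2. The regions without a knockout locus were narrower, with a median width of 939 against 9946 bases. Among regions under 3000 bases the shares were 76.4% and 19.8%, and 76.4% and 29.6% after matching on width, a ratio of 2.58. The ratio of 5 set in advance was out of reach there, since the highest possible was 3.38. That reads from repeated sequence were kept in the wild-type tables and not in the knockout table therefore stays open. Too few reads in the knockout are argued against by its depth, 11.8 times the implied fragments of the mean wild-type table. A difference in genotype stays open and untested, and cannot be told apart from a difference in read length or processing.

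Within chromosome X, the IgG ChIP windows did not gather in repeated sequence, as judged by the mapping quality of IgG DIP reads. In the X windows 32.5% of IgG DIP reads had a mapping quality under 30, and in random placements on X the median was 46.1% (95% of placements 39.8% to 55.5%). These placements stay on X, so they cannot tell whether X as a whole holds more windows because of repeated sequence. Over all IgG DIP reads the share with a mapping quality under 30 was 20.7%. The list has no partner sample here, so no biological explanation was tested.

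It was also asked, as a hypothesis, whether IgG ChIP windows gather in transcribed regions. They did not. Of the 1730 windows, 8.61% (exact binomial interval 7.33% to 10.0%) overlapped a knockout RNA locus, against a median of 12.8% over 1000 random placements on the same chromosomes (95% of placements 11.2% to 14.4%), the comparison set in advance. For wild-type loci the share was 3.35% against 4.97%. With placements only in bins with reads, the choice first run, the medians were 12.8% and 4.97%. Fewer windows than chance met RNA loci in both cases, with a one-sided permutation p of 0.001, the smallest these placements can give; this direction was chosen after the values were seen.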
